A study of Mus musculus with 6 samples.

How the data were processed

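RNA from the kidneys of male mice lacking the orphan nuclear receptor ERRα (ERRa KO) and of wild-type (WT) males was hybridised to Affymetrix mouse expression arrays, 1 array per sample. The labels give 3 biological replicates per genotype and an age of 2 to 3 months. Per the labels, both kidneys of a mouse were powdered together under liquid nitrogen, total RNA was extracted on columns, and biotin-labelled cRNA was hybridised. The labels call the replicates biological and do not say in words that each is another animal. The number of arrays, 3 per genotype, limits the precision of every value.

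The expression values are log2 values made by the authors with RMA, per the submitters' processing notes. The settings of that RMA run are not given in the sources used here. RMA corrects the background, quantile normalizes the arrays and summarises the probes of a probe set, so array-wide differences in brightness are removed before deposit and low levels are compressed. The arrays had medians between 5.02 and 5.06 on the log2 scale over the 45101 probe sets. The deposited values came in a series table keyed by sample and in an authors' table headed by genotype and replicate. That second table also holds the authors' log2 fold change and the authors' unadjusted p-value for each probe set, with the test not stated in the file header.

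The 2 tables name the genotypes in opposite ways. The 3 columns headed WT in the authors' table hold, for 45101 of 45101 probe sets, the values that the series table gives to the 3 ERRa KO samples, and the columns headed ERRa KO hold those of the WT samples. The authors' own fold change column, headed as KO against WT, follows the series table to within 7.8e-07, and differs from its own column heads by up to 5.86. The genotype of each array was therefore taken from the series table, by sample, and not from the values. The opposite assignment was kept as an alternative, added after the data were seen. The authors' p-value equals an equal-variance test of the same 6 values to within 2.8e-05.

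Of the 45101 probe sets, 64 are hybridisation controls and were left out, leaving 45037. A platform annotation names 1 gene for 34945 of these, several for 932 and none for 9160. Probe sets with several names or none were left out of the gene table. Gene identifiers were checked against an annotation table of the GRCm38.p6 assembly, in which 34741 probe sets were found by identifier. No genome was used and no coordinates are given. That table served only for names and to find which genes neighbour each other. A gene was represented by its probe set with the highest mean over all 6 arrays, which gave 18193 genes. Ren1, on the list of genes to report, is not analysed here.

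Changes were tested on the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, genotype as the only term). Benjamini-Hochberg adjustment ran over the 18193 genes, or over the 45037 probe sets in a separate fit. An adjusted p under 0.05 was the threshold. Differences are ERRa KO minus WT on the log2 scale, with the standard error (SE) of the fit. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, over the lists with at least 5 measured genes. The test was repeated with an estimated correlation and with limma's fry, a rotation test of a list on its own. For each list the members past the threshold were counted over all genes and adjusted over the list alone. These tests used no pseudocount and no filter on low values.

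The groups, the tests, 30 gene lists and the rule for the genes to be named were fixed before the data were examined. The rule takes the 10 largest rises and the 10 largest falls among genes past the threshold whose values do not overlap between genotypes. It adds Esrra, Esrrb, Esrrg, Ppargc1a, Ppargc1b, Ren1 and Agt, and up to 4 members with the smallest p from each list that has a member past the threshold, or up to 2 from a list without one. It also adds members asked for by a count of 5 or fewer, here Kcnj1, Bsnd and Alas2. The other genes in the closing section, and Alb, were chosen after their values were seen. Lists of liver, plasma cell, cell cycle, matrix, fibroblast and clock-limb transcripts were written after the data were seen, the fibroblast list before the values of its members were, and appear only in the closing section, apart from the liver list.

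Any pair of arrays held at most 131 identical values of 45101, and all 6 arrays counted as separate samples. Correlations between arrays over all genes ran from 0.994 to 0.998. The fit and the list test were tested on simulated data with the 18193 genes. Of genes changed by 0.5 on the log2 scale, 67% were recovered, of those changed by 1.0, 95%, and 7 unchanged genes were called. A simulated list shifted by 0.3 was called, and 0 of the unshifted lists were. The simulated genes were drawn independently, while the estimated correlation within the fixed lists reached 0.58. The simulation therefore cannot show how often camera at the preset correlation calls unshifted lists of correlated genes.

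Alternatives were array quality weights, a trended and robust prior, renewed quantile normalization, median centring, a filter on dim probe sets, other choices of probe set, the replicate number as a block, a threshold of 0.1, and leaving out each array in turn. The alternative of using the other table of values had no separate numbers to give, because both tables hold the same values. Python 3.11.15 with pandas 2.3.3 read the tables and drew the plots with matplotlib 3.10.9.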

Results

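The data compare whole-kidney transcript levels between male mice without ERRα, a nuclear receptor that acts with the coactivators PGC-1α and PGC-1β on genes of mitochondrial energy metabolism, and WT males. There were 3 ERRa KO and 3 WT arrays, each with log2 RMA values for 45101 probe sets. The question, from the series title, is which genes differ in the kidney between these genotypes. Because whole kidneys were ground, each value mixes all cell types of the organ.

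Esrra, the targeted gene, was lower in all 3 ERRa KO kidneys. The brighter of its 2 probe sets read 9.46 ± 0.05 (SD, n = 3) in WT and 6.53 ± 0.13 (SD, n = 3) in ERRa KO kidneys, a fall of 7.62-fold (log2 change -2.93, SE 0.08, limma adjusted p = 9.85e-06). The dimmer probe set read 6.12 ± 0.14 in WT and 5.03 ± 0.08 in ERRa KO kidneys, a log2 change of -1.09. The part of the gene removed in these mice is not given in the labels, so a probe set may lie outside it. The genotypes used here are those of the series table. Under the column heads of the authors' table, which are exchanged, every direction in the text would turn and Esrra would read higher in ERRa KO kidneys. The fold change column in the authors' deposited table gives -2.93 for the brighter probe set, the same direction as here.

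**Figure D1:**
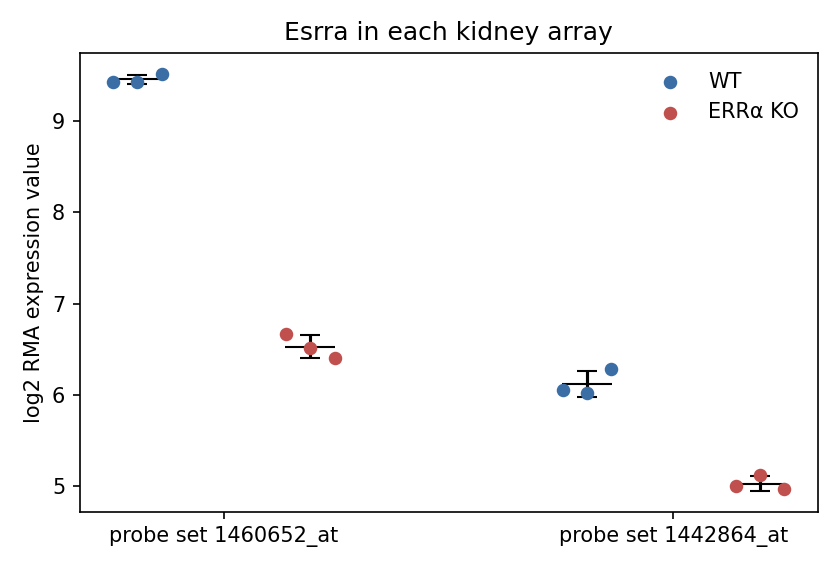
Log2 RMA expression value (vertical axis) of the 2 Esrra probe sets in each of the 6 kidney arrays, 3 WT (blue) and 3 ERRa KO (red); black lines give the mean and the bars the SD. For the brighter probe set the ERRa KO mean is 6.53 and the WT mean 9.46, with no overlap.

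Across the kidney, 90 of 18193 genes changed, 49 higher and 41 lower in ERRa KO. Of these, 17 changed by 2-fold or more, 13 higher and 4 lower, and the smallest change called was 1.28-fold. The largest rise was that of Atp4a, the catalytic subunit of the gastric proton-potassium pump, at 2.89-fold (7.89 ± 0.11 in WT, 9.41 ± 0.05 in ERRa KO, SD, n = 3; log2 change 1.53, SE 0.07, adjusted p = 0.000381). The cytochrome P450 genes Cyp2d12 and Cyp2d9 rose by 1.46 and 1.36 on the log2 scale (adjusted p = 0.0400 and 0.00688). The neurofilament gene Nefl rose by 1.36, the vesicle-priming gene Unc13b by 1.34 and the neurogenic transcription factor gene Neurog2 by 1.31. Completing the 10 largest rises were the cell adhesion gene Cadm4 (1.29), the carbonic anhydrase gene Car3 (1.17), the secreted glycoprotein gene Azgp1 (1.13) and the clock output gene Dbp (1.12).

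After Esrra, the largest fall was that of Top2a, a topoisomerase of proliferating cells, by 1.28 (SE 0.17, adjusted p = 0.033), the proliferation marker Mki67 fell by 0.99 (adjusted p = 0.0258), and the mitotic kinase gene Pbk fell by 0.82 (adjusted p = 0.0494). The fibrillar collagen gene Col3a1 fell by 1.19 (SE 0.12, adjusted p = 0.0156) and another, Col5a2, by 1.15 (SE 0.09, adjusted p = 0.00688). The other falls among the 10 largest were Asb11, which encodes a ubiquitin ligase adaptor (-0.92), the monoacylglycerol acyltransferase gene Mogat2 (-0.85), the imprinted noncoding RNA Airn (-0.76) and the glucuronosyltransferase gene Ugt2b37 (-0.76). Weak expression limits some of these values: the WT means of Top2a, Mki67 and Pbk were 5.67, 5.97 and 5.80, and those of Nefl and Neurog2, among the largest rises, 3.86 and 4.80.

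**Figure D2:**
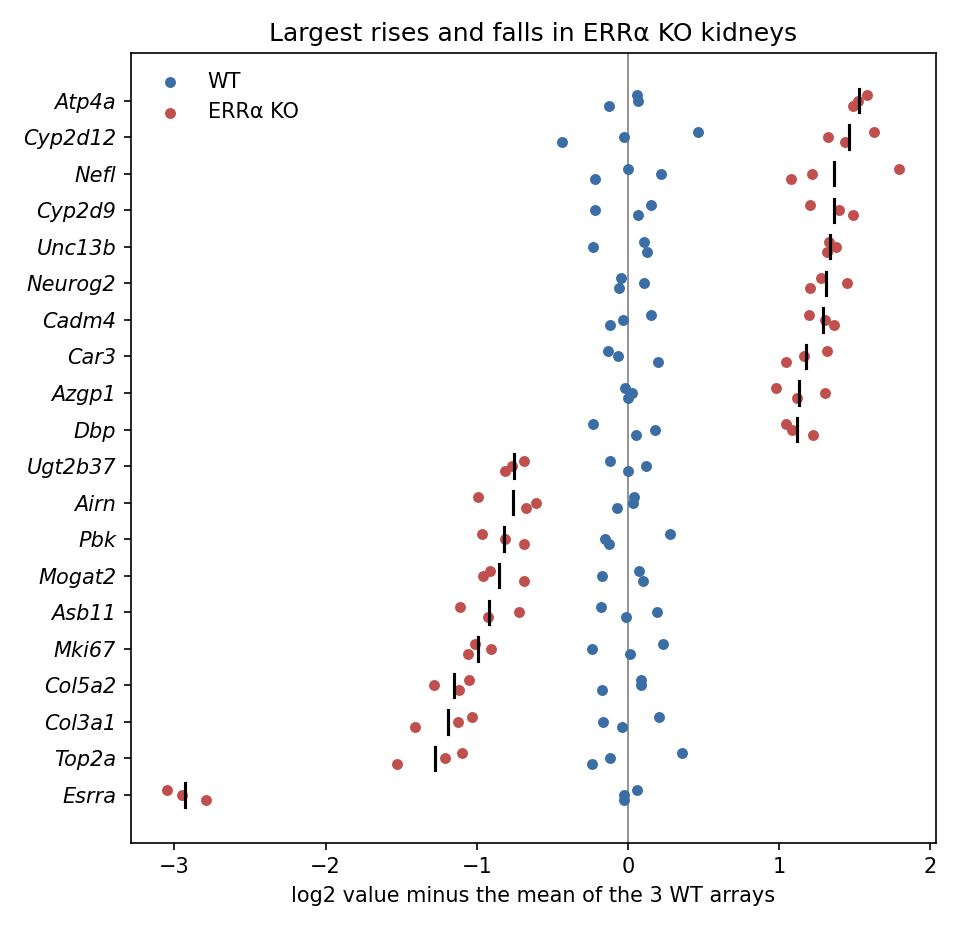
Log2 value minus the mean of the 3 WT arrays (horizontal axis) for the 10 genes that rose most and the 10 that fell most; each point is 1 array, blue for WT and red for ERRa KO, and the black line is the ERRa KO mean. The ERRa KO points do not overlap the WT points in any of these genes, as the rule for choosing them required, and Esrra lies farthest from 0 at -2.93.

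In all 90 called genes the ERRa KO values did not overlap the WT values, which passing the threshold with 3 arrays per genotype nearly requires. The same held for 18.7% of all genes, against 10% by chance for a gene on its own. Genes vary together, so the distance between these 2 shares was not tested. At the level of probe sets 50 of 45037 changed, 29 higher and 21 lower, and 33 of the 36 genes they name were also called in the gene table. The calls rest on few arrays: leaving out 1 array left between 10 (without WT replicate 1) and 39 (without ERRa KO replicate 3) called genes, with 13 without WT replicate 2, 28 without WT replicate 3, 25 without ERRa KO replicate 1 and 12 without ERRa KO replicate 2. Besides Esrra, 7 of the other 30 called genes named here stayed past the threshold in each of these fits, namely Atp4a, Azgp1, Cadm4, Col5a2, Cyp2d9, Neurog2 and Unc13b. Of the 31 called genes named here 16 have several probe sets. Signs were opposite in 2 of 4 probe sets of Car3, 2 of 5 of Airn and 1 of 3 of Top2a and Col1a2 each. None of those had an unadjusted p under 0.05. The fall of Airn rested on its brightest probe set, with changes of 0.06, 0.04, -0.10 and -0.02 in the others, all dimmer. Averaging all probe sets of a gene ended the calls of Airn, Arntl, Car3, Col1a2, Pfkp and Top2a. Cyp2d and Ugt2b genes belong to families of near-identical copies, so which member their probes read is uncertain.

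1 array stood apart. In ERRa KO replicate 3, 21 of 22 measured liver transcripts, a list written after the data were seen, read highest of the 6 arrays, with a median 2.61 above the other 5 arrays on the log2 scale. The albumin gene Alb read 12.07 there and between 6.48 and 6.80 in the other 5 arrays. Without that array 39 genes were called, 31 higher and 8 lower, and 28 of them were among the 90. Of the 14 lists called, 12 were still called without it.

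Of the 30 gene lists, 28 had enough measured genes, and camera called 14 of them, 5 higher and 9 lower in ERRa KO kidneys. With an estimated correlation 0 of the 28 were called by camera: the smallest adjusted p was 0.218, and 2 lists had an unadjusted p under 0.05. Limma's fry called 4 lists: the clock list, the immediate early and heat shock list, the xenobiotic list and the ERR family list, of which Esrra is a member. The lists that follow are described in the order of the receptor's own family, energy metabolism, transport and endocrine genes, the clock, stress and matrix genes, and cell types.

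Apart from Esrra, none of the 13 other measured members of the ERR family and coregulator list passed the threshold (limma). Values were -0.15 (adjusted p = 0.378) for Esrrb, 0.08 (adjusted p = 0.632) for Esrrg, -0.14 (adjusted p = 0.347) for Ppargc1a, which encodes PGC-1α, -0.01 (adjusted p = 0.99) for Ppargc1b, and 0.25 (adjusted p = 0.216) for Ppara. Esrrg changed sign when all its probe sets were averaged. The list as a whole was not called by camera (adjusted p = 0.289). None of the 19 measured genes next to Esrra on its chromosome passed the threshold by either adjustment, and 2 had an unadjusted p under 0.05, Trmt112 (0.24) and Trpt1 (0.16). That list was not called (camera adjusted p = 0.175). It reached 0.0482 without ERRa KO replicate 3, and up to 0.305 when another array was left out.

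Respiratory chain transcripts were slightly lower as a group. Some cell-type lists described below shifted by more. Thick ascending limb (median -0.15), distal tubule (-0.21), intercalated cell (-0.22) and smooth muscle markers (-0.20) read lower, and podocyte markers higher (0.20). The respiratory chain genes were not tested apart from such shifts. Of 34 measured genes of complex I, the NADH dehydrogenase, 29 read lower and 5 higher in ERRa KO kidneys with a median log2 change of -0.06, and camera called the list lower (adjusted p = 9.99e-05; adjusted p = 0.449 with an estimated correlation). None of the 34 passed limma's threshold, either over all genes or adjusted over the list alone, and 8 had an unadjusted p under 0.05; Ndufb10 read -0.24 (SE 0.05, adjusted p = 0.129) and Ndufb7 -0.20 (SE 0.05, adjusted p = 0.183). Of 43 measured genes of complexes II to V and cytochrome c, 33 read lower with a median of -0.05, and this list too was called lower (adjusted p = 0.00451; adjusted p = 0.449 with an estimated correlation). The 1 member past the threshold went the other way: Cox8b, a cytochrome oxidase subunit of heart, skeletal muscle and brown fat, rose by 1.06 (SE 0.13, adjusted p = 0.0328). Over the list, 3 members were higher and 0 lower when adjusted over the list alone, the others being the muscle-type subunits Cox7a1 (0.40) and Cox6a2 (0.48). The brown fat gene Ucp1, of the adipocyte list, read 1.18 higher in ERRa KO kidneys with widely spread WT values (SD 0.95, adjusted p = 0.32).

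Other mitochondrial lists were not called. In the citrate cycle and pyruvate dehydrogenase list 0 of 25 genes passed limma's threshold and 5 had an unadjusted p under 0.05 (camera adjusted p = 0.155), and adjusted over the list alone Pdk2, a kinase that restrains pyruvate dehydrogenase, was higher (0.33, adjusted p over all genes = 0.109); Idh2 read -0.22. In fatty acid oxidation 0 of 27 passed by either adjustment and 5 had an unadjusted p under 0.05 (camera adjusted p = 0.322), with Acaa2 at 0.41 (adjusted p = 0.146) and Fabp3 at 0.24 (adjusted p = 0.213). When 1 array was left out, that list was called lower only without ERRa KO replicate 1, at a camera adjusted p of 0.00657. The other omissions gave up to 0.919. Mitochondrial import, dynamics and ribosome genes had 0 of 27 past the threshold by either adjustment and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.41), with Mrpl34 at -0.19 and Polrmt at -0.12. Of 11 targets of PPARα outside beta-oxidation 0 passed and 4 had an unadjusted p under 0.05 (camera adjusted p = 0.99), and adjusted over the list alone the lipid droplet gene Plin2 was higher (0.26). Cyp4a14, a fatty acid hydroxylase gene, read -1.77 (SE 0.74, limma adjusted p = 0.386). Its change passed the threshold only without ERRa KO replicate 1 (adjusted p = 0.0352), which alone among the ERRa KO arrays read near the WT level. Other omissions of 1 array gave Cyp4a14 an adjusted p of up to 0.653. The median and mean of the PPARα list were negative while its test pointed up.

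Sodium and potassium transport genes read lower as a group. Of 31 measured genes 22 were lower and 9 higher, with a median of -0.07, and the list was called lower (adjusted p = 0.0134; adjusted p = 0.449 with an estimated correlation). No member passed the threshold over all genes, and 9 had an unadjusted p under 0.05. When adjusted over the list alone 4 were lower, the potassium channel genes Kcnq1 (-0.42, adjusted p over all genes = 0.0654) and Kcnj1, the chloride channel subunit gene Bsnd and the sodium channel subunit gene Scnn1g (-0.30), and 1 was higher, the glucocorticoid-responsive Tsc22d3 (0.39). The call ended without ERRa KO replicate 1 (adjusted p = 0.0897) and without ERRa KO replicate 2 (0.0556), and also above the median level, while without ERRa KO replicate 3 the median was -0.12 and the adjusted p 0.000585. The list shares members with the thick ascending limb, distal tubule and collecting duct lists; the first 2 of these were also called lower, with medians of -0.15 and -0.21, and the transport genes were not tested apart from them. Of the renin-angiotensin system 0 of 12 measured genes passed by either adjustment and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.666), with angiotensinogen, Agt, at 0.22 (SE 0.09, adjusted p = 0.393) and the aminopeptidase gene Anpep at -0.30 (adjusted p = 0.405).

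In the list of water channels and the vasopressin response 1 of 12 genes changed: the vasopressin receptor gene Avpr1a fell by 0.56 (SE 0.07, adjusted p = 0.033). In that list 4 were lower adjusted over the list alone, with Aqp6 (-0.62, adjusted p over all genes = 0.0668), Avpr2 (-0.35) and Aqp8 (-0.25), and 1 was higher. The list was called at an adjusted p of 0.0486 (adjusted p = 0.545 with an estimated correlation), and the call ended when any array except WT replicate 1 was left out, with adjusted p up to 0.377. It ended as well with the replicate block, with array quality weights, with quantile normalization, above the median level and with fry.

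In glycolysis and gluconeogenesis 2 of 19 genes rose, both glycolytic: the phosphofructokinase gene Pfkp by 0.90 (SE 0.09, adjusted p = 0.0145) and the aldolase gene Aldoa by 0.50 (SE 0.06, adjusted p = 0.0307). The pyruvate kinase gene Pkm (-0.23) was lower when adjusted over the list alone, while Hk2 read 0.32 (adjusted p = 0.289). The list was not called (camera adjusted p = 0.402). Of 15 xenobiotic and steroid metabolism genes 2 rose and 1 fell: Cyp2d9, the quinone reductase gene Nqo1 (0.50, adjusted p = 0.0328) and Ugt2b37. The counts adjusted over the list alone were 5 higher and 2 lower, with Cyp27a1 at 0.32. This list was called higher (adjusted p = 0.0206; adjusted p = 0.341 with an estimated correlation), and no longer without ERRa KO replicate 3, the array with liver transcripts (adjusted p = 0.109), or without WT replicate 2. Of 9 androgen-responsive kidney genes Cyp2d9 alone passed; Acsm3 read -0.18, Timd2 0.25 and Slco1a1 -0.10. That list was not called (adjusted p = 0.666), and its median was slightly negative while its mean and test were positive.

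Most clock genes read higher, 16 of 20, and 4 read lower. Of the 20 measured genes of the circadian clock and its outputs, Dbp (1.12, SE 0.11, adjusted p = 0.0145), the period gene Per2 (1.04, SE 0.12, adjusted p = 0.0274) and Ciart, a repressor of the clock activators (0.59, SE 0.08, adjusted p = 0.0414), rose. Arntl, which encodes the clock activator BMAL, fell by 0.71 (SE 0.09, adjusted p = 0.033). There were 13 genes higher and 1 lower adjusted over the list alone, and the list had a median of 0.39. Camera called it higher with the smallest p of all lists (adjusted p = 3.14e-07; adjusted p = 0.268 with an estimated correlation), and without ERRa KO replicate 3 the median was 0.39 again. Calls of single members were less firm: Ciart and Arntl lost theirs when any 1 array was left out. Collection times of the kidneys are not given in the labels.

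**Figure D3:**
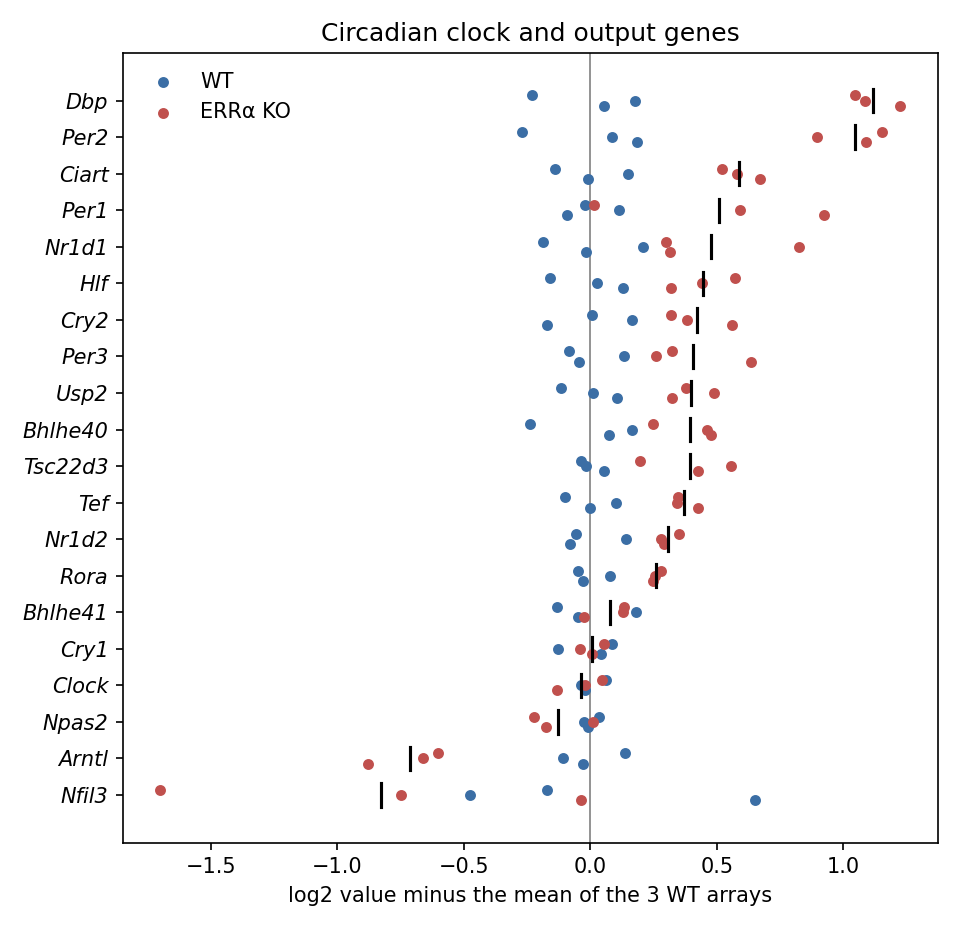
Log2 value minus the mean of the 3 WT arrays (horizontal axis) for the 20 measured genes of the clock list, ordered by their change; each point is 1 array, blue for WT and red for ERRa KO, and the black line is the ERRa KO mean. Dbp, Per2 and Ciart lie at the top and Arntl near the bottom, each with no overlap between genotypes.

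Immediate early and heat shock transcripts read higher in 16 of 17 genes, with a median of 0.27. The early growth response gene Egr1 rose 2.0-fold (log2 change 1.00, SE 0.14, adjusted p = 0.0400), and adjusted over the list alone 5 genes were higher, including the heat shock genes Hspa1a (0.96, adjusted p over all genes = 0.0674), Hspa1b (0.75) and Dnajb1 (0.51). The list was called higher (adjusted p = 4.18e-05; adjusted p = 0.218 with an estimated correlation). In the injury and fibrosis list 3 of 17 genes fell, all collagens: Col3a1, Col1a2 (-0.62, SE 0.07, adjusted p = 0.0213) and Col4a1, of basement membrane (-0.56, adjusted p = 0.0328). Col1a1 was lower as well when adjusted over the list alone (-1.02, adjusted p over all genes = 0.0832). The list was called lower (adjusted p = 0.00634; adjusted p = 0.449 with an estimated correlation), with a median of only -0.02 (-0.04 without ERRa KO replicate 3), and the call ended without ERRa KO replicate 1 (adjusted p = 0.0638).

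Markers of several kidney cell types read lower or higher as groups, with no single member past limma's threshold in the gene table. Intercalated cell markers had a median of -0.22, with 11 of 12 lower (camera adjusted p = 7.26e-06; adjusted p = 0.361 with an estimated correlation); adjusted over the list alone 7 were lower, among them Aqp6 and the anion exchanger gene Slc4a1 (-0.40; another of its probe sets was called in the probe set fit, at -0.72, adjusted p = 0.0249), and 7 had an unadjusted p under 0.05. Thick ascending limb markers had a median of -0.15 (-0.23 without ERRa KO replicate 3), with 9 of 11 lower (camera adjusted p = 0.00019; adjusted p = 0.449 with an estimated correlation) and 4 lower over the list alone and at an unadjusted p under 0.05, among them the claudin gene Cldn16 (-0.38, adjusted p over all genes = 0.052) and the prostaglandin receptor gene Ptger3 (-0.42). Distal convoluted and connecting tubule markers had a median of -0.21, with 7 of 8 lower (camera adjusted p = 0.000685; adjusted p = 0.449 with an estimated correlation) and 3 lower over the list alone, 5 members having an unadjusted p under 0.05, among them the kallikrein gene Klk1 (-0.26) and the calcium buffer gene Calb1 (-0.55). Smooth muscle and pericyte markers had a median of -0.20, with 7 of 8 lower (camera adjusted p = 0.000441; adjusted p = 0.341 with an estimated correlation) and 4 lower over the list alone and at an unadjusted p under 0.05, among them Tagln (-0.33) and Mylk (-0.21).

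Podocyte markers went the other way, with all 7 higher and a median of 0.20 (camera adjusted p = 0.00244; adjusted p = 0.341 with an estimated correlation). The cell cycle inhibitor gene Cdkn1c was higher when adjusted over the list alone (0.37), Synpo read 0.20, and 3 members had an unadjusted p under 0.05. Proximal tubule markers, of the most abundant cell type of the kidney, were not called (adjusted p = 0.666), with 10 of 20 on either side of 0; adjusted over the list alone 3 were higher, including the transporter genes Slc5a2 (0.26) and Slc22a8 (0.23), and 2 were lower. Collecting duct principal cell markers were not called (adjusted p = 0.692), with Scnn1g and Avpr2 lower over the list alone and a median of the opposite sign to the mean and test. Endothelial markers were not called (camera adjusted p = 0.197), with Tek at -0.22 and Plvap at -0.17. Of the 10, 0 passed by either adjustment and 2 had an unadjusted p under 0.05. The list reached a camera adjusted p of 0.0433 without WT replicate 3, and up to 0.874 when another array was left out.

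Among cells from outside the nephron, 0 of 14 immune cell markers passed and 8 had an unadjusted p under 0.05 (camera adjusted p = 0.666). Of these 3 were higher and 3 lower adjusted over the list alone, among them the macrophage complement gene C1qc (-0.32) and the immunoglobulin joining chain gene Jchain (2.24). Jchain had an SE of 0.52 and a limma adjusted p over all genes of 0.135. It passed only without ERRa KO replicate 3 (0.00915), with up to 0.346 when another array was left out. Adipocyte markers of perirenal fat were called higher by camera (adjusted p = 0.0145, and 0.449 with an estimated correlation). Of the 8 members 7 read higher and 1 lower, and Car3 was the only 1 past limma's threshold. The median was 0.10, and 0.17 without ERRa KO replicate 3. Lep read 0.22 and Pparg -0.20, and the call ended without WT replicate 2 (adjusted p = 0.204) and without ERRa KO replicate 1 (0.0873), and also with the mean of all probe sets. Adrenal markers were not called (adjusted p = 0.738), with Chga higher over the list alone (0.25) and Pnmt at -0.22. Blood cell markers had 4 measured genes and were not tested as a list. Over all genes 0 passed, and over the list alone 3 did. Of these Alas2 (0.96) and Hbb-b2 (0.39) were higher, and Slc4a1, which the kidney also expresses, was lower (-0.40). The values of Alas2 overlapped between genotypes. Of 4 genes that differ between males and females, 0 passed and 0 had an unadjusted p under 0.05, with Xist at 0.10 and Uty at 0.07.

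**Figure D4:**
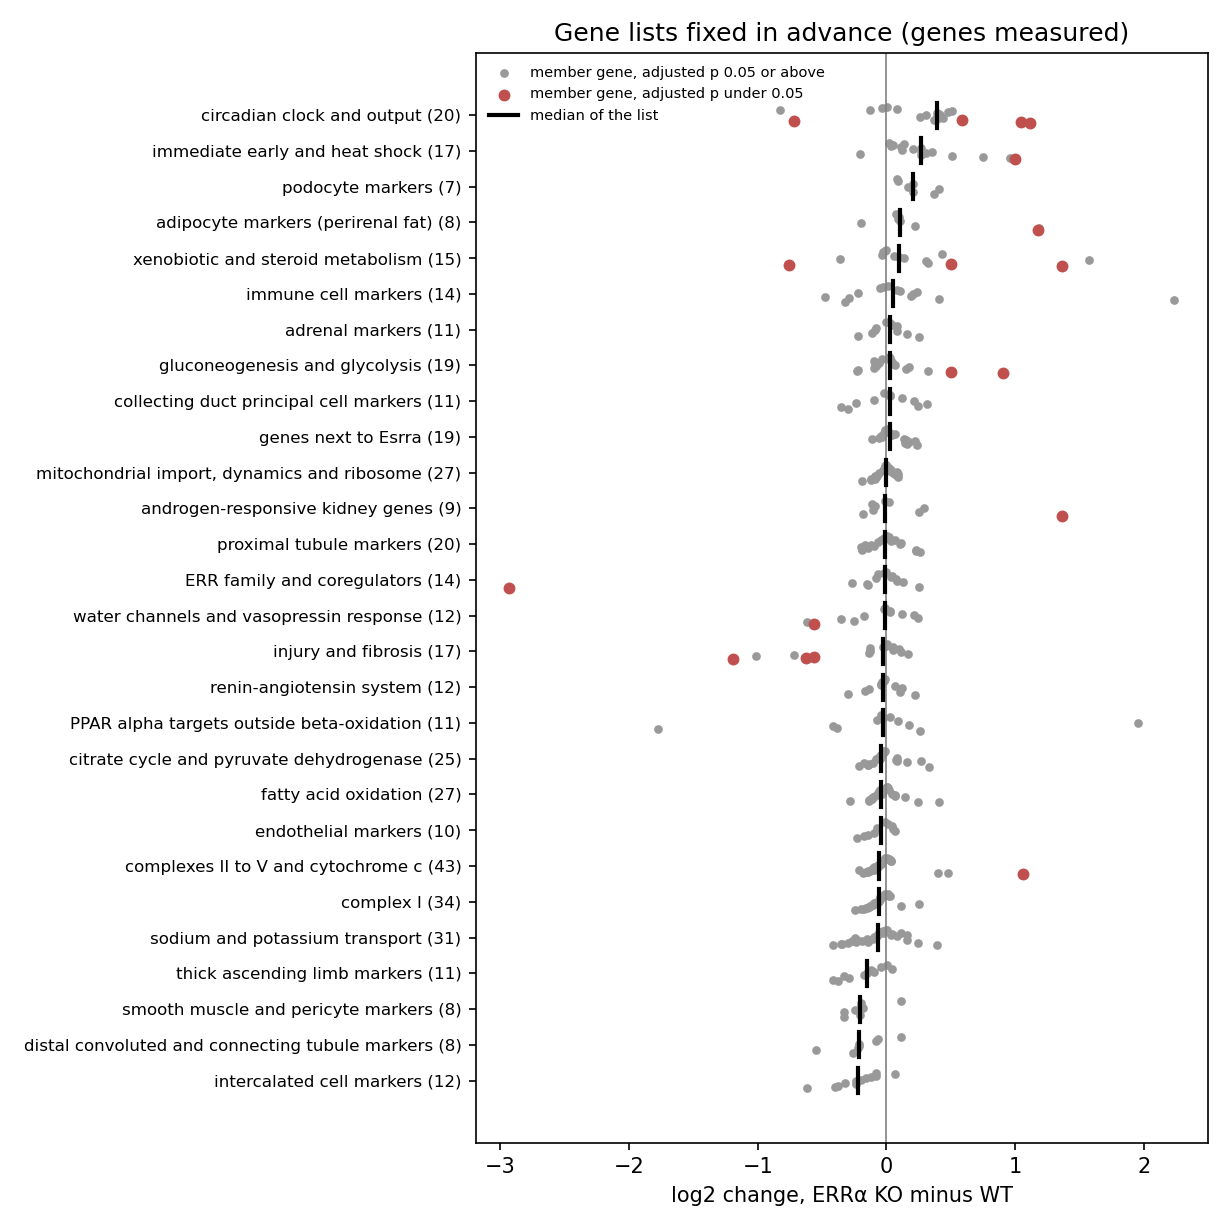
Log2 change of each measured gene, ERRa KO minus WT (horizontal axis), for the 28 tested gene lists, with the number of measured genes in brackets; grey points are members at an adjusted p of 0.05 or above, red points members under 0.05, and black bars the list medians. The clock list has the highest median, 0.39, and the intercalated cell list the lowest, -0.22.

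The authors' deposited table gives an unadjusted p under 0.05 for 4294 probe sets, 2074 higher and 2220 lower in ERRa KO by its fold change column, and 0 after Benjamini-Hochberg adjustment of that p, where the limma fit of the same values called 50.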

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

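Of the alternatives, the column heads of the authors' table were added, and the planned omission of ERRa KO replicate 3 was singled out, after the data were seen. Esrra kept its direction and its call in every alternative except those column heads, under which 90 genes are called with all directions turned and Esrra reads 2.93. Leaving out each array in turn gave 10 to 39 genes (7 to 31 higher, 3 to 8 lower) and 7 to 35 probe sets (4 to 25 higher, 3 to 10 lower). Those fits have fewer arrays. All 90 genes kept their direction in each, which was fixed in advance because their values do not overlap between genotypes. More genes were called with array quality weights (133, of which 78 higher; 89 of the 90 among them), with a trended and robust prior (379: 192 higher, 187 lower; 88 of the 90), with probe sets above the median level (220: 115 higher, 105 lower; all 63 of the 90 still tested, with fewer genes to adjust over) and at a threshold of 0.1 (239: 124 higher, 115 lower). The probe set counts were 92 (49 higher, 43 lower) with weights, 437 (221 and 216) with that prior, 99 (49 and 50) with median centring, 143 (70 and 73) above the median level and 173 (84 and 89) at a threshold of 0.1. The causes of the other shifts were not tested.

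Same-numbered arrays did not deviate together (correlations of their deviations -0.04, -0.003 and -0.08), so the numbers gave no sign of a pairing. Arrays of different numbers had correlations from -0.07 to 0.10. With 3 arrays per genotype, a pairing cannot be excluded in this way. A replicate block gave 18 genes (11 higher, 7 lower) and 3 probe sets (2 higher, 1 lower), with fewer degrees of freedom. With an estimated correlation 0 lists were called, with adjusted p of 0.449 for complex I, for complexes II to V and for sodium and potassium transport and 0.268 for the clock list. Fry called 4 lists, with 0.0648 for complex I and for complexes II to V and 0.205 for sodium and potassium transport. The sodium and potassium list had adjusted p between 0.000585 and 0.0897 when 1 array was left out, and 0.104 above the median level.

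Results not past the threshold turned direction as follows, the cause not tested. The PPAR alpha target list had adjusted p of 0.798 with the replicate block, 0.754 with weights, 0.969 with quantile normalization, 0.982 with median centring, 0.746 above the median level, 0.657 without WT replicate 2 and 0.222 without ERRa KO replicate 1; it kept its direction in the other 4 omissions, and all 6 gave 0.222 to 0.983. Above the median level the renin-angiotensin list (0.608) and the proximal tubule and collecting duct lists (0.995 each) turned. Each of 3 lists turned in 1 omission only: immune cell markers without WT replicate 2 (0.700; 0.187 to 0.915 over the 6 omissions), collecting duct markers without WT replicate 3 (0.425; 0.166 to 0.907) and proximal tubule markers without ERRa KO replicate 2 (0.911; 0.529 to 0.911). The log2 change of Ppargc1b turned in 4 omissions and ran from -0.107 to 0.0688 over the 6. Esrrg read -0.11 with the mean of all its probe sets. Of 30 called named genes besides Esrra, 23 lost the call in at least 1 omission of an array, 17 with the replicate block, 6 with the mean of all probe sets, 1 (Pbk) with quantile normalization and 1 (Cyp2d12) with the trended prior. Signal near the background limits the weakly expressed genes: 27 of the 90 had a mean under the median level of 6.45.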

Other observations

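The tests in this part were all chosen after the results they bear on were seen, except the test of fibroblast transcripts and the splits of the arrays. The lists of matrix, cell cycle, plasma cell, liver and clock-limb transcripts, and the other genes named in this part, were likewise chosen after their values were seen, so their camera results describe these arrays and are no independent evidence of direction. Each bootstrap interval in this part resamples the members of a list and not the arrays. It gives the spread over members and not the spread between mice. Members can vary together: the estimated correlation was 0.82 for the liver list, 0.37 for the clock negative limb and 0.07 for the matrix list. What these intervals argue against is therefore argued for these arrays only.

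Transcripts of the extracellular matrix read lower in ERRa KO kidneys beyond the collagens already named. All 23 measured matrix genes had a negative change, with a median of -0.31, and 8 fell by limma's test over all genes. Besides Col3a1, Col5a2, Col1a2 and Col4a1 these were Col4a2 (-0.44), the collagen chaperone gene Serpinh1 (-0.45), the collagen-modifying enzyme gene Plod2 (-0.61) and the matrix glycoprotein gene Sparc (-0.36). With an estimated correlation this list had a camera adjusted p of 0.0193 (unadjusted p = 0.00276). That adjustment, like the one for the cell cycle list, ran only over the lists written after the data were seen. It is therefore not comparable with the adjusted p of the lists fixed in advance. Genes already called are among the members. Of 23 cell cycle genes 22 read lower, with a median of -0.37. Top2a and Mki67 fell, and 17 were lower adjusted over the list alone (adjusted p = 0.0819 with an estimated correlation).

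Some immunoglobulin transcripts differed between arrays. The heavy chain gene Igha read between 6.85 and 7.07 in the WT arrays and 9.78, 10.2 and 7.93 in ERRa KO replicates 1, 2 and 3 (log2 change 2.39, SE 0.52, adjusted p = 0.114). Jchain (2.24) and the light chain gene Igkv8-30 (2.11) had the same order of arrays. Without ERRa KO replicate 3, Igha had an adjusted p of 0.00212. The heavy chain gene Ighm did not change (0.01, adjusted p = 0.949), and the B cell genes Ms4a1 and Cd79a read -0.09 and 0.19. The cytokine-signalling gene Socs2 read 9.50 in ERRa KO replicate 1 and 7.38 and 6.93 in the other 2, against 8.47 to 9.63 in WT, and Cyp4a14 read 8.69, 5.66 and 5.89 against 7.92 to 8.88. Bhmt, a methyl transfer enzyme gene, read 5.75, 5.88 and 7.96 in the ERRa KO arrays and a mean of 4.90 in WT (adjusted p = 0.258, and 0.0158 without ERRa KO replicate 3).

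In ERRa KO replicate 3, of 22 measured transcripts known from liver, 21 read highest of the 6 arrays; 9 of the 22 also had a WT mean above 6.45, the median level of all genes. On that array 61 genes stood 2-fold or more above all others, among them 15 of the liver list, with Alb at 12.07, Apoa1 at 9.08 and Fabp1 at 8.96. An effect of the genotype on the list as a whole is argued against by the other 2 ERRa KO arrays, whose median over the list was -0.0373 from WT (bootstrap interval -0.11 to 0.10). Single members differed both ways in those 2 arrays. Apob (0.54) and Apoc3 (0.55) read higher than WT and Fga (-0.57) lower, with limma adjusted p of 0.188, 0.163 and 0.154. Over all 6 arrays 2 of the 22 had an unadjusted p under 0.05, and 1 was higher adjusted over the list alone. Array scaling would move genes of the same level alike. The list exceeded the 50 genes nearest in level to each member by a median of 2.56 (bootstrap interval 1.20 to 3.30). RMA had already evened out the levels between arrays, and the list was written because it stood out on this array. That comparison could therefore hardly have come out otherwise and does not decide on array scaling. The values, 21 of 22 highest there, are consistent with liver RNA in that sample, as a hypothesis; how it came there was not tested.

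The clock genes may differ because of the genotype or because the kidneys of the genotypes were taken at different times of day. Without ERRa KO replicate 3 the median change of the 11 genes of the negative limb and its outputs was 0.45 (bootstrap interval 0.38 to 0.76), which argues against liver RNA in that array as the whole cause. The negative limb lay 0.57 above the 5 genes of the positive limb, whose median was -0.13. A shift in collection time and an effect of ERRα on the clock both allow such an opposition, so they cannot be told apart without recorded collection times. The higher Egr1 and heat shock transcripts were not tested against either.

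For the lower matrix and cell cycle transcripts, dilution by liver RNA as the whole cause is argued against: without ERRa KO replicate 3 the matrix median was -0.34 (bootstrap interval -0.48 to -0.15). That criterion and the like one for the clock genes were set after the values were seen. They replaced stricter ones, that most of the change be kept, which the matrix interval did not settle. Leaving out that array moved the matrix median from -0.31 to -0.34 and the cell cycle median from -0.37 to -0.39. Neither moved toward 0, the direction that a part played by dilution would give. Both shifts lie within the spread over members, so dilution as a part of the cause was not excluded. A lower share of fibroblasts would lower their other transcripts as well. All 8 listed genes, not all of them particular to fibroblasts, read lower, with a median of -0.0835 (bootstrap interval -0.16 to -0.03). Changes ran from -0.02 for Thy1 and -0.05 for Pdgfra to -0.19 for Cd34. Only 1 of the 8, Cd34, had an unadjusted p under 0.05 by limma. The camera adjusted p of the 8 genes over the lists written afterwards was 0.0442, and 0.188 with an estimated correlation. Thy1, Pdgfrl and Gli1 among them were weak, with WT means of 4.18, 3.77 and 4.08, and low levels are compressed. The fibroblast median neither matches the matrix median of -0.31 nor excludes a contribution. Smooth muscle and pericyte markers, of cells that also make matrix, read lower too (median -0.20, with 0 of 8 past the threshold over all genes and adjusted p = 0.341 with an estimated correlation and 0.0708 with fry). A lower share of these cells was not tested. Older ERRa KO mice within the age range of 2 to 3 months could lower both groups, as the cell cycle median of -0.37 allows; the age of each mouse is not given. An effect of the genotype itself cannot be told apart from that difference in age.

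The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 90 genes, 50 probe sets and 14 lists, and the highest of the other splits gave 0 genes, 0 probe sets and 9 lists, so in each case 1 of the 10 splits, the real one, was as large. Every other split mixes the genotypes, so differences between genotypes widen the spread and low gene counts are likely there. Camera at the preset correlation still called lists in other splits, as many as 9, 8 and 6. That limits what the 14 calls of the real split show.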
